A study of Mus musculus with 12 samples.

How the data were processed

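DNA methylation was read by reduced representation bisulfite sequencing (RRBS), which covers CpG-rich fragments of the genome. Per the labels, the 12 libraries come from female mouse embryonic fibroblasts (MEFs) of embryonic day 13.5 with Cre-ERT2, a Cre recombinase switched on by 4-hydroxytamoxifen (4-OHT). The cells were either Braf wild type or Braf+/LSL, in which Cre activates 1 Braf allele. Each genotype has 3 clones. Per the labels, every clone was read at day 0, without 4-OHT, and at day 21, after 0.1 µM 4-OHT for 7 days, with replating every 3 days in 10% serum. The strain is given as mixed.

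The values used are the authors' deposited read counts per cytosine: per the file headers, the count of C reads and of C plus T reads, and the same for G and A on the opposite strand. The column names are those that the methratio step of BSMAP writes. Per the submitters' processing notes, CASAVA 1.8.2, BSMAP 2.89 and limma were used with the mouse builds mm10 and GRCm38. The rules for filtering reads and the handling of PCR duplicates are not given in the sources used here, and reads copied by PCR are not independent molecules. The authors also deposited a table of 874381 windows of 200 bp, placed every 50 bp, with a difference of changes, a p-value and an adjusted p-value per window. Judged by its values, the 6 ratio columns of the authors' deposited table were quantile normalized, because the largest gap between their sorted values was 0.0235 and the median gap 1.82e-07. No column of per-sample values was left without a sample (0).

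From the deposited counts, CpG cytosines with at least 10 reads in every one of the 12 libraries were kept, each strand on its own. This left 1011155 cytosines, with a median of 69 to 91 reads per cytosine in a library. The libraries held 99655263 to 203876695 reads over CpG cytosines in all, and 82783666 to 114965234 over those kept. They were summed over fixed 200 bp windows with at least 3 such cytosines (114618 windows, of which 114616 were tested) and over promoters with at least 5 (11358 genes on 10734 distinct regions). A promoter reaches from 1000 bp outside to 500 bp inside a gene end. The annotation in hand (GRCm38.p6) gives the ends of genes and no strand, so the gene end with more CpG cytosines in reach was taken. The plan had asked for the 5-prime-most start. A region called a promoter here may therefore lie at the end where transcription stops. For Cdkn2a the end taken is not the start of exon 1-alpha, from which p16 is transcribed, because that start lies inside the gene.

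Methylated and unmethylated read counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 coverage term per library and all 12 libraries sharing 1 estimate of the spread. p-values were adjusted by the Benjamini-Hochberg method over all windows or all promoters of a comparison. A region was called where the adjusted p was under 0.05 and the group means differed by at least 10 percentage points. The 3 comparisons of change (day 21 against day 0 in Braf cells, the same in wild type, and the difference between these changes) had clone as a block. The 2 comparisons of genotype, at day 0 and at day 21, had no block. Group values are means of the 3 libraries with the standard deviation (SD). limma 3.58.1 ran beside edgeR on log ratios and on percentages. Other alternatives tried were 5 or 30 reads per cytosine, windows of 1000 bp, promoters of 500 bp to each side or at both gene ends, no block, thinned reads, other sizes of difference, autosomes alone, unconverted reads subtracted, and each clone left out. In a further one, cytosines with over 10% A on the opposite strand were left out as possible sequence variants.

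The labels' design text says that the repeats used different clones, so the 2 days of a repeat number were taken as 1 clone. The values fit this: within a genotype, the residuals of each day 21 library correlated best with the day 0 library of its own number (r = 0.307, 0.362 and 0.397 in wild type; 0.556, 0.573 and 0.786 in Braf). Across genotypes, libraries of the same number and day gave r from -0.00265 to 0.101, so the genotypes were not paired. The p-values for single regions and for means per library measure only the spread between these clones. Those for gene lists by camera or by random lists also rest on the spread between genes. The 2 comparisons of genotype, which had no block, counted the 2 days of a clone as independent when the spread was estimated. Their p-values may therefore be too small.

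Counts were simulated for up to 20000 of the windows, with changes put into the Braf day 21 libraries alone. Their estimated dispersion was 0.0311 and 0.0339, against 0.0161 in the data, so the shares called may differ in the data. In simulated counts with 200 changed windows, 45 of 67 changes of 20 points in Braf were called, with 1 false call among 19798 unchanged windows. For the difference between the changes of the genotypes, 9 of 67 differences of 20 points and 43 of 66 differences of 40 points were called. With 3000 changed windows, 950 of 1000 changes of 20 points in Braf and 720 of 1000 differences of 20 points between the changes were called.

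The 19 gene lists were tested on promoters with camera of limma (preset correlation 0.01, on log2 of methylated over unmethylated reads, 1 added to each), adjusted over the lists. Camera asks whether a list moves more than the other promoters do. It was run again with the correlation estimated from the data, and fry of limma, which asks whether a list changes at all, was run beside it. The lists are Hox genes, other developmental transcription factors, clustered protocadherins, endothelial, epithelial, blood cell, neural and muscle markers, fibroblast and mesenchymal genes, inflammatory and secretory genes, Wnt antagonists, imprinted genes, germline genes, cell cycle inhibitors and senescence, MAPK pathway and its feedback genes, orthologues of human CpG island methylator phenotype markers, tumour suppressors often methylated in cancer, DNA methylation machinery, and housekeeping genes as a reference. Means per library were compared by exact permutation tests, two-sided. These cannot give p under 0.25 for the change of 3 clones or under 0.1 for 3 against 3.

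Genes to be named were fixed by a rule. Among called promoters it takes the 10 largest gains and losses that go the same way in all 3 clones, the 5 largest each way between genotypes, and up to 4 called members per list. Cdkn2a, Cdkn2b, Igfbp7 and Braf are always given (1 further gene of the rule is not reported here), and windows are given by the 3 largest each way. Genes with only a model number were passed over: 9 among the gains in Braf, 1 among its losses, 16 among the gains in wild type, and 1 among the lower promoters at each day. The comparisons, the tests, the thresholds, the lists and this rule were chosen before the data were examined. The gene end, the treatment of unconverted reads and the tests of the closing section were chosen afterwards. The positions of sequence variants could not be checked against a genome, because no genome sequence was in hand. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9 did the remaining work, with version 1.17.8 of the R package data.table.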

Results

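The Braf promoter, at the gene that carries the LSL allele, was almost unmethylated in all 4 groups, from 1.12% ± 0.87 (Braf day 0) to 3.43% ± 5.3 (wild type day 21; SD, n = 3). Braf encodes a kinase that relays growth signals from Ras to MEK. Its promoter methylation does not show whether Cre has recombined the allele, and RRBS counts do not measure that. Day 21 cells differ from day 0 cells in 4-OHT, in Cre activity and in 21 days of culture, so each change below holds all of these, and only the difference between genotypes sets the activated allele apart.

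In Braf cells, most promoters that changed by day 21 gained methylation. Dlx1, a homeobox gene of the developing forebrain, and Rara, the gene of retinoic acid receptor alpha, led the gains. Mdk, which encodes the growth factor midkine, and Prdm1, a repressor of transcription in germ cells and lymphocytes, gained as well, as did Foxl1, a forkhead gene of the gut mesenchyme. Olfr403 and Olfr43, 2 neighbouring olfactory receptor genes, lost methylation. The Dlx1 promoter (chromosome 2, 71527113 to 71528613) rose from 25.8% ± 4.48 to 56.9% ± 10.1 (SD, n = 3; median 701 reads per library). The Rara promoter (chromosome 11, 98926800 to 98928300) rose from 29.8% ± 5.9 to 60.1% ± 7.33, and the Mdk promoter (chromosome 2, 91931797 to 91933297) from 15% ± 2.02 to 42.8% ± 5.05. Gains of 25.1 to 28.6 points were seen at Actl10, Marveld2, Prdm1, Cxcl3, Asb4, Dkk3 and Foxl1. Dkk3, a secreted Wnt antagonist, varied most between clones, at 39% ± 19.6 on day 21. Olfr403 (chromosome 11, 74195946 to 74197446) fell from 73.8% ± 1.68 to 48.8% ± 3.2 and Olfr43 from 71.9% ± 0.545 to 48.1% ± 1.6. Mag, a myelin gene, Lcn9, Vmn1r229, a pheromone receptor gene, Caskin1, Skint11, A1cf, Magea8 and Ffar1 changed by -17.5 to -11.9 points.

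By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 199 of 11358 promoters were called in Braf cells (181 gains, 18 losses; 195 distinct regions). The adjusted p by this quasi-likelihood test was 6.41e-07 at Dlx1, 6.41e-07 at Rara, 7.63e-08 at Mdk, 5.01e-05 at Olfr403 and 3.33e-05 at Olfr43. Several losses lost their call when a clone was left out, at differences of -17.3 to -10.6 points. In the same quasi-likelihood test without Braf clone 1, the adjusted p was 0.0889 at Mag, 0.156 at Magea8 and 0.0584 at Ffar1. Without Braf clone 2 the quasi-likelihood test gave an adjusted p of 0.0581 at Mag, 0.0864 at Magea8, 0.0702 at Vmn1r229, 0.444 at Caskin1 and 0.0843 at Skint11. Without Braf clone 3 the quasi-likelihood test gave an adjusted p of 0.127 at Magea8, 0.118 at Vmn1r229 and 0.194 at Caskin1, and without wild-type clone 2 of 0.0772 at Caskin1. When clone was not used as a block, no promoter (0) was called by edgeR at this threshold, with 347 at an unadjusted p under 0.05, while limma on percentages without the block called 164. With unconverted reads subtracted edgeR called 0 promoters (1280 at an unadjusted p under 0.05) and limma on percentages 168.

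Markers of other cell types were among the gains in Braf cells. Developmental transcription factors, which set cell identity in the embryo, gained at Dlx1, at Tbx5, a limb and heart gene (17.8% ± 2.19 to 33.7% ± 10.4), at Tfap2a, a neural crest gene (6.41% ± 1.22 to 21% ± 7.48), and at Tbx1 (10.5% ± 2.21 to 24.9% ± 7.03). Endothelial markers gained at Esam, a junction gene (37% ± 1.98 to 55.1% ± 2.83), Lyl1, a blood and vessel factor (40.8% ± 3.66 to 56.9% ± 5.73), and Nos3, the endothelial nitric oxide synthase (73.4% ± 3.23 to 85.3% ± 2.28). Epithelial markers gained at Marveld2, a tight junction gene, and at the keratins Krt7 (40.8% ± 5.9 to 57.3% ± 1.56) and Krt18 (21.9% ± 3.94 to 33.8% ± 2.39). Secreted factors gained at Tgfb1 (31% ± 3.32 to 49.7% ± 4), and at the neutrophil chemokines Cxcl5 (9.16% ± 0.979 to 28.9% ± 2.19) and Cxcl2 (9.34% ± 1.52 to 24.1% ± 6.71). Protocadherins, which give neurons their identity at the surface, gained at Pcdhga8, Pcdhga9, Pcdhga10 and Pcdhgb7, by 13 to 16 points. Single members of other lists gained too: Hoxa2 (15.1% ± 2.67 to 35.4% ± 11.6), the Wnt antagonist Dkk3, the muscle gene Des (15.2% ± 0.82 to 35% ± 2.11), the imprinted gene Rasgrf1 (5.02% ± 0.853 to 17.6% ± 2.11) and the germline gene Hormad2 (41.7% ± 2.69 to 54.1% ± 2.26).

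By camera with its preset correlation, 9 of 19 lists passed in Braf cells. The developmental transcription factors had 5 of 80 members called (adjusted p = 1.80e-11; adjusted p = 0.494 with an estimated correlation), and the endothelial markers had 3 of 9 (adjusted p = 6.58e-07; adjusted p = 0.0944 with an estimated correlation). The protocadherins had 4 of 27, on 17 regions (adjusted p = 1.20e-06; adjusted p = 0.437 with an estimated correlation), and 0.0386 with each region entered once. The epithelial markers had 3 of 16 (adjusted p = 0.000386; adjusted p = 0.437 with an estimated correlation). Camera gave an adjusted p of 0.0396 for 5 lists: Hox genes (1 of 28 called; adjusted p = 0.437 with an estimated correlation), inflammatory and secretory genes (3 of 11; adjusted p = 0.521 with an estimated correlation), neural markers (0 of 12; adjusted p = 0.521 with an estimated correlation), Wnt antagonists (1 of 12; adjusted p = 0.558 with an estimated correlation) and the housekeeping genes. The housekeeping genes (0 of 18; adjusted p = 0.521 with an estimated correlation) tested lower than other promoters although their mean change was 0.502 and their median change 0.150 points. None of these lists kept its call with the estimated correlation. Without Braf clone 3, 4 lists passed camera, and without each of Braf clone 1, Braf clone 2 and wild-type clone 1, 6 passed.

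The lists of silenced tumour genes did not pass camera in Braf cells. Camera's adjusted p was 0.131 for the orthologues of methylator phenotype markers (0 of 12 called), 0.890 for the tumour suppressors (0 of 20), 0.131 for the MAPK list (0 of 31), 0.453 for cell cycle inhibitors and senescence (0 of 21) and 0.643 for the DNA methylation machinery (0 of 16). It was 0.550 for blood cell markers (0 of 7), 0.656 for fibroblast and mesenchymal genes (0 of 16), 0.643 for germline genes (1 of 29), 0.643 for imprinted genes (1 of 28) and 0.261 for muscle markers (1 of 8). Camera's direction against other promoters was lower for the MAPK list, cell cycle inhibitors and germline genes, none of which passed. Their median changes were 0.163, 0.185 and 1.26 points. By fry, which asks whether a list changes at all, 14 of 19 lists passed in Braf cells and 16 in wild type, among them, in Braf cells, the orthologues of methylator phenotype markers (adjusted p = 0.0228 by fry, 0.131 by camera) and the DNA methylation machinery (adjusted p = 0.0348 by fry, 0.643 by camera). In every list, the count of called members adjusted over the list alone was the same as over all promoters. Some members lost their call when a clone was left out, at differences of 9.08 to 14.9 points. In the quasi-likelihood test the adjusted p was 0.106 at Hormad2, 0.228 at Krt18, 0.055 at Pcdhgb7 and 0.0528 at Pcdhga10 without Braf clone 1. The quasi-likelihood test without Braf clone 2 gave an adjusted p of 0.0539 at Hormad2, 0.122 at Krt18, 0.0662 at Pcdhga10, 0.140 at Pcdhga9 and 0.0777 at Nos3, and without Braf clone 3 of 0.119 at Hormad2 and 0.0556 at Tbx5.

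The promoters of Cdkn2a, Cdkn2b and Igfbp7 stayed under 5% in every group. Cdkn2a and Cdkn2b encode inhibitors of the cell cycle, and Igfbp7 a secreted protein tied to senescence. In Braf cells the Cdkn2a promoter was at 1.96% ± 0.316 on day 0 and 3.63% ± 0.85 on day 21 (n = 3), with an adjusted p of 0.00349 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a difference of 1.68 points, under the 10 required. Cdkn2b was at 1.2% and 1.16%, and Igfbp7 at 1.44% and 2.32%. In wild type, Cdkn2a was at 2.53% and 4%, Cdkn2b at 2.07% and 2.18%, and Igfbp7 at 1.93% and 2.98%. No comparison called any of these promoters or that of Braf.

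The largest window gains in Braf cells lay at the far end of Cdkn2a and in Dlx1. The window at chromosome 4, 89274801 to 89275000, inside the Cdkn2a gene, rose from 18.2% ± 3.18 to 63.6% ± 6.78, and the one at 89274001 to 89274200, just outside, from 12.3% ± 3.58 to 53.5% ± 5.64. These lie at the end away from the CpG-dense end of the gene, whose windows had group means of 4.01% at most. In Dlx1 the window at chromosome 2, 71532401 to 71532600, rose from 12.2% to 53.7%. The largest losses lay far from genes: nearest Tafa5 (chromosome 15, 87221601; -43 points), Cdh9, a cadherin gene (chromosome 15, 15278601; -38.3 points), and Gm46320 (chromosome 12, 106443801; -35.5 points). Windows within 1000 bp of a gene end mostly gained (749 gains, 71 losses), and so did windows under 20% methylated (657 gains, 8 losses). Windows outside genes mostly lost (1404 gains, 2628 losses), as did those at 80% or more (198 gains, 942 losses) and those on chromosome X (37 gains, 424 losses). The directions of calls under 20% and at 80% or more are partly set by the rule for a call, which asks for a smallest difference. A window with little methylation can hardly lose that much, and one with high methylation can hardly gain it. Windows from 20% to 80% had 3480 gains and 2669 losses in Braf cells. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7954 of 114616 windows in Braf cells, 4335 gains and 3619 losses. The count was 4964 without Braf clone 1, 5200 without Braf clone 2 and 2673 with clone not used as a block.

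In wild-type cells, which have no allele to activate, the same promoters led the gains. Mdk rose from 12.6% ± 2.03 to 51.8% ± 2.85, Rara from 26% ± 2.83 to 63.3% ± 7.7, and Dlx1 from 20.7% ± 4.97 to 57.3% ± 4.82 (SD, n = 3). Them7, Fxyd7, a regulator of the sodium pump, Prdm1, Tmem200b, Isyna1, the inositol synthase gene, Marveld2 and Crb2, a polarity gene, gained 29.4 to 35.9 points. Olfr43 fell from 75.8% ± 3.93 to 57.7% ± 3.2 and Olfr403 from 73.9% ± 3.97 to 61% ± 7.53. Itgal, a leukocyte integrin gene, Fcrl5, Tspoap1, Ptpn3, Ripor2, Krt35 and Ctu1 changed by -12.5 to -10.5 points.

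By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 271 promoters were called in wild type (262 gains, 9 losses; 247 distinct regions), with an adjusted p of 1.13e-10 at Mdk, 1.75e-08 at Rara, 1.99e-08 at Dlx1 and 0.00078 at Olfr43. Among the 9 losses only Olfr43 kept its call whichever clone was left out. The quasi-likelihood test without wild-type clone 1 gave an adjusted p of 0.415 at Itgal, 0.227 at Fcrl5 and 0.165 at Tspoap1, and differences of -7.69 points at Ripor2 and -4.68 points at Ctu1. Without wild-type clone 2 the quasi-likelihood test gave an adjusted p of 0.309 at Olfr403, 0.25 at Krt35 and 0.138 at Ptpn3. Without wild-type clone 3 it gave 0.154 at Itgal, 0.0522 at Olfr403, 0.0849 at Fcrl5, 0.0787 at Tspoap1 and 0.081 at Ptpn3 as adjusted p by the quasi-likelihood test. Leaving out a Braf clone alters the shared spread, and the quasi-likelihood test then gave an adjusted p of 0.065 (Braf clone 1), 0.0744 (Braf clone 2) and 0.0708 (Braf clone 3) at Itgal, 0.0503 at Olfr403 (Braf clone 2) and 0.0524 at Krt35 (Braf clone 3). With no block, 13 promoters were called. With unconverted reads subtracted edgeR called 0 promoters (1188 at an unadjusted p under 0.05) and limma on percentages 217.

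In wild type, Hox genes, which pattern the body axis, gained at Hoxa3 (28.9% ± 6.76 to 57% ± 9.36), Hoxa2 (17.2% ± 4.49 to 43.4% ± 11.4), Hoxa5 (17.6% ± 2.93 to 33.5% ± 8.72) and Hoxc10 (15.2% ± 4.34 to 30.7% ± 6.07). The developmental transcription factors gained at Dlx1, at Pitx1, a hindlimb gene (7.86% ± 2.03 to 19.4% ± 2.28), Hand1 (10.2% ± 2.21 to 21.6% ± 5.47) and Tfap2a (7.25% ± 3.09 to 18% ± 3.4). The imprinted gene Nnat gained (40.3% ± 5.05 to 64.5% ± 4.77), as did Rasgrf1 (5.4% ± 2.5 to 17.8% ± 2.97). Tagln, a smooth muscle and fibroblast gene, gained (3.97% ± 2.82 to 14.2% ± 7.75), as did the germline gene Stag3, the muscle gene Des (15.5% ± 1.49 to 35.7% ± 6.86), Tgfb1 (31.3% ± 2.42 to 56.2% ± 3.11), Cxcl2 and Dkk3. Krt7, Krt18, Esam, Nos3 and Lyl1 gained 12.3 to 18.9 points. Pcdhga2, Pcdhga4, Pcdhga11 and Pcdhga12 share 1 region at the common end of the cluster (chromosome 18, 37841373 to 37842873), which rose from 7.31% ± 3.92 to 24.9% ± 9.52. Being an end that these genes share, it need not be where each of them starts.

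By camera, 10 of 19 lists passed in wild type, all higher. The developmental transcription factors had 5 of 80 called (adjusted p = 7.86e-11; adjusted p = 0.329 with an estimated correlation), the Hox genes 6 of 28 (adjusted p = 0.00610; adjusted p = 0.260 with an estimated correlation), and the endothelial markers 3 of 9 (adjusted p = 0.000420; adjusted p = 0.260 with an estimated correlation). The protocadherins had 15 of 27 called, on 5 of 17 regions (adjusted p = 4.04e-07; adjusted p = 0.276 with an estimated correlation), but with each region entered once their adjusted p was 0.0794. The epithelial markers had 3 of 16 (adjusted p = 0.000157; adjusted p = 0.276 with an estimated correlation), the inflammatory and secretory genes 2 of 11 (adjusted p = 0.000420; adjusted p = 0.276 with an estimated correlation), and the Wnt antagonists 1 of 12 (adjusted p = 0.000420; adjusted p = 0.330 with an estimated correlation). The neural markers had 0 of 12 (adjusted p = 0.00365; adjusted p = 0.305 with an estimated correlation), the fibroblast and mesenchymal genes 1 of 16 (adjusted p = 0.0123; adjusted p = 0.492 with an estimated correlation) and the muscle markers 1 of 8 (adjusted p = 0.0123; adjusted p = 0.276 with an estimated correlation).

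The other 9 lists did not pass camera in wild type. Camera's adjusted p was 0.682 for the orthologues of methylator phenotype markers (0 of 12 called), 0.682 for the tumour suppressors (0 of 20), 0.670 for the MAPK list (0 of 31), 0.923 for cell cycle inhibitors and senescence (0 of 21) and 0.914 for the DNA methylation machinery (0 of 16). It was 0.328 for blood cell markers (0 of 7), 0.682 for germline genes (1 of 29), 0.170 for housekeeping genes (0 of 18) and 0.712 for imprinted genes (2 of 28). Camera's direction against other promoters was lower for the MAPK list, cell cycle inhibitors, germline genes and housekeeping genes, none of which passed. Their mean changes were 0.698, 0.773, 1.76 and 0.912 points. Counts adjusted over the list alone were again the same. Some members fell under 10 points when a clone was left out: without wild-type clone 1 the differences were 9 points at Stag3 and 8.62 at Tagln, and without wild-type clone 3, 8.4 at Tagln and 9.75 at Hand1, with an adjusted p of at most 0.00107 by the quasi-likelihood test. The quasi-likelihood test without wild-type clone 2 gave an adjusted p of 0.172 at Esam and 0.0826 at Lyl1, and without wild-type clone 3 of 0.115 at Krt18 and 0.0695 at Nos3, at differences of 8.46 to 11.5 points.

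The largest window gains in wild type were again at the far end of Cdkn2a, and then in Meis1, a homeobox partner of Hox proteins. The Cdkn2a windows rose from 12.6% ± 3.09 to 81.2% ± 7.13 (89274001) and from 15.6% ± 3.36 to 78.4% ± 1.97 (89274801). The Meis1 window at chromosome 11, 19016601 to 19016800, rose from 16.7% ± 2.19 to 73.2% ± 2.62. The largest losses lay in Homer2, a synaptic scaffold gene (chromosome 7, 81627601; -34.6 points), in Kirrel3, a neural adhesion gene (chromosome 9, 35032601; -30.4 points), and nearest Sdhaf3 (chromosome 6, 7180401; -30.4 points). The quasi-likelihood test with Benjamini-Hochberg adjustment called 7867 windows, 6173 gains and 1694 losses. Gains outnumbered losses within 1000 bp of a gene end (949 to 44), in windows under 20% (1124 to 9), outside genes (1953 to 1246) and at 80% or more (419 to 302), and chromosome X had 41 gains and 171 losses. Over all windows the mean change was nonetheless -0.583 points outside genes and -0.454 at 80% or more. Here too the directions of calls under 20% and at 80% or more are partly set by the rule for a call. The quasi-likelihood test gave an adjusted p of 0.0561 at Homer2 and 0.165 at Kirrel3 without wild-type clone 2, and of 0.0919 at Kirrel3 without wild-type clone 3. The count was 2896 with no block. Wild-type clone 3 read more non-CpG cytosines as methylated than the rest (4.94% and 6.77%), and without it 5786 windows were called.

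**Figure D1:**
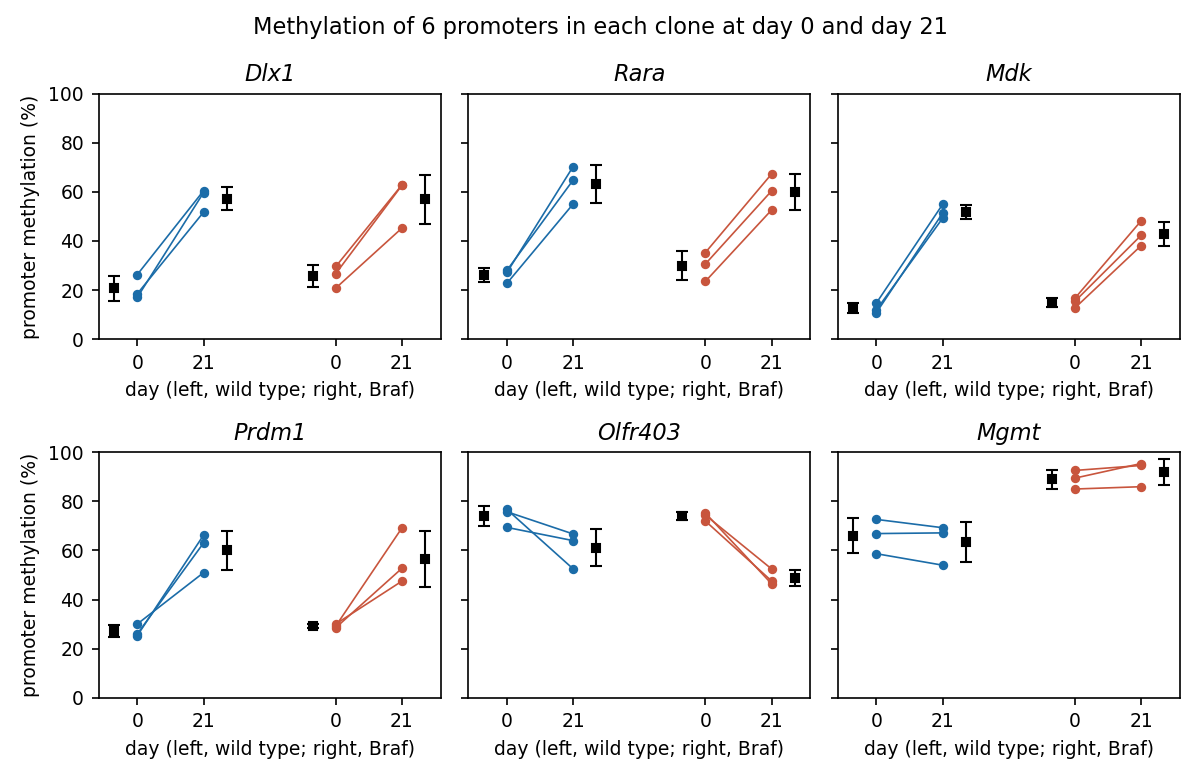
Methylation of 6 promoters, each at the gene end with more CpG cytosines, at day 0 and day 21, 1 line per clone, wild type and Braf side by side. Dlx1, Rara, Mdk, Prdm1 and Olfr403 come from the naming rule for the changes and Mgmt from that for the genotypes.

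The 2 genotypes changed alike at most places, and in the main analysis no single promoter or window passed the test for a different change in Braf. Of the promoters that gained, 143 did so in both genotypes, among them Dlx1, Rara, Mdk, Marveld2 and Prdm1, where 4.18 shared promoters would come by chance if the genotypes were independent. Olfr403 and Olfr43 were the 2 shared losses. Of the windows, 3316 gained and 1185 lost in both genotypes. The changes of the genotypes correlated over windows (r = 0.775) and over promoters (r = 0.806), although neighbouring regions are not independent.

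Windows in Bicc1 and Meis1 had the lowest p-values for a difference of change. They and the further genes of this paragraph, which were picked from many windows with higher p-values, are named after their values were seen. In Meis1, 2 windows were at 28.5% and 81.7% in wild type against 23.8% and 27.3% in Braf (chromosome 11, 19014201 to 19014400), and at 16.7% and 73.2% against 15.2% and 26.4% (19016601). Calls around Meis1 were not fewer in Braf: of the 23 windows there, 8 were called as gains in Braf and 4 in wild type. These counts do not test a difference of change. In Bicc1, an RNA-binding gene of the kidney, the window at chromosome 10, 71049601 was at 64.8% and 92.4% in wild type against 63.3% and 57.3%. The same direction was seen in Tgif2 and Meis2, both homeobox genes, with differences of -17 and -22 points. In Dusp5, a phosphatase gene that ERK signalling induces, the window at chromosome 19, 53530401 was at 25.6% and 48.7% in wild type against 26.8% and 15.7%. Zfp566 had a window with the opposite direction (62.5% and 59.7% against 65% and 88.3%).

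By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 windows were called for the difference of changes, with 8205 at an unadjusted p under 0.05, and limma called 0 on log ratios (8840 at an unadjusted p under 0.05) and 0 on percentages (8516). The lowest adjusted p by the quasi-likelihood test was 0.0707, at Bicc1, followed by 0.103 and 0.167 at Meis1, while Dusp5 had 0.27 and Zfp566 0.269. For promoters edgeR called 0, with 380 at an unadjusted p under 0.05, and limma called 0 and 0 (503 and 353 at an unadjusted p under 0.05). Of the 8205 windows, 5834 had changed further down in Braf and 2371 further up. In simulated counts this comparison called 9 of 67 differences of 20 points when 200 of 19998 windows differed, and 720 of 1000 when 3000 of 20000 did. The simulated set was smaller than the 114616 windows tested here, so 3000 windows were a larger share of it. Windows of 1000 bp gave 3 calls and thinned reads 1, all 4 further down in Braf. Without wild-type clone 3, 2 promoters were called, those of the neighbouring genes Eva1b and Sh3d21 (seen only afterwards).

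Within gene lists, Hoxa3, Hoxc10, Nnat and Cxcl5 stood out for the difference of changes, again after the values were seen. Hoxa3 and Hoxc10, patterning genes, and Nnat, an imprinted gene of the brain, had smaller changes in Braf (differences of -19.3, -11.9 and -16.7 points), and Cxcl5, a chemokine gene, a larger one (15 points). Adjusted over the list alone, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.0173 at Hoxa3, 0.0175 at Hoxc10, 0.0442 at Nnat and 0.0119 at Cxcl5. Over all promoters the quasi-likelihood test gave an adjusted p of 0.945 at Hoxa3, Hoxc10 and Cxcl5 and 0.9995 at Nnat. By camera 0 lists passed, with 4 at an unadjusted p under 0.05 (fibroblast and mesenchymal genes, Wnt antagonists, protocadherins and endothelial markers), and fry called 0. Camera's lowest adjusted p was 0.0924, for the fibroblast and mesenchymal genes, followed by 0.155 for Wnt antagonists, protocadherins and endothelial markers. The count was 1 without Braf clone 3, 2 without wild-type clone 2, 2 without wild-type clone 3 and 3 with no block.

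The authors' deposited table tests the same difference and has 0 of 874381 windows with an adjusted p under 0.05 (smallest 0.475) and 51305 with p under 0.05. Its difference column is wild type minus Braf, in 100% of windows, although it carries the name of Braf. Over the 86909 windows also tested here, the difference in the authors' deposited table correlated with that of edgeR at a Spearman coefficient of -0.672, the sign following from the order of subtraction. Both gave p under 0.05 at 1810 windows (325 if independent), and 1807 of these had the same direction.

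**Figure D2:**
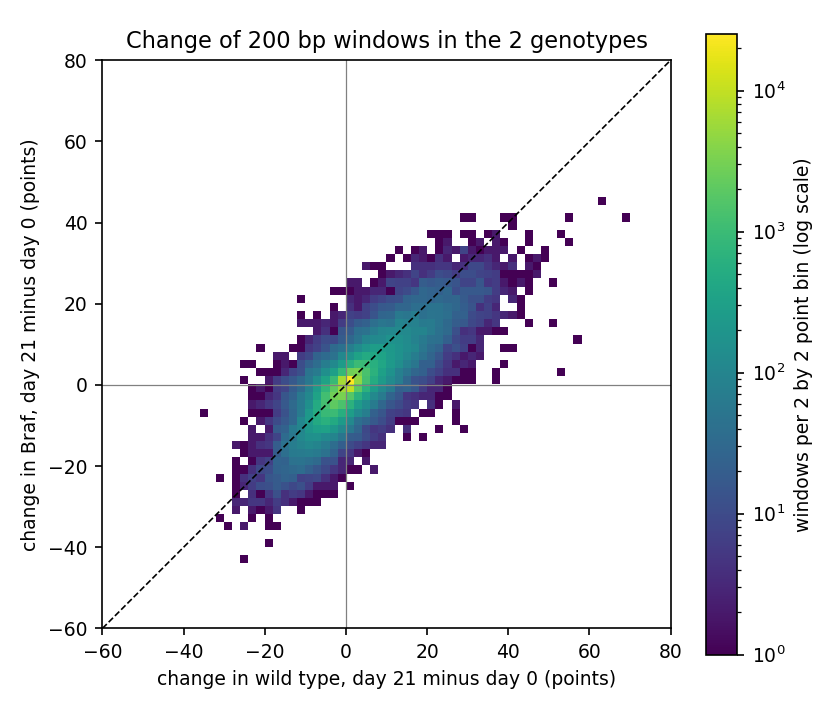
Change in methylation from day 0 to day 21 of 200 bp windows in wild type against that in Braf, shaded by the number of windows.

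Before any 4-OHT, a few promoters were already less methylated in Braf cells than in wild type. Kdm5b, a histone demethylase gene, was at 1.51% ± 1.06 against 22.8% ± 12.5 (chromosome 1, 134559178 to 134560678; n = 3 each), and Tomm5, a gene of the mitochondrial import pore, at 0.955% ± 0.645 against 18.4% ± 3.89. Gpi1, a glycolysis gene, was at 1.1% ± 0.519 against 18.4% ± 2.02. Prdx2, a peroxiredoxin gene, and Rnaseh2a share most of their region and were at 1.07% ± 0.471 against 22.2% ± 6.07. A window near Cep250, a centrosome gene (chromosome 2, 155988201 to 155988400), was higher in Braf (90.6% ± 0.11 against 26.4% ± 1.87), as were windows near Zfp954 and Gm52512 (53.7 and 53.5 points). Windows near Ctnnbl1, Gm8773 and Etv4, an ETS factor gene of the MAPK list, were lower (-43.6, -32 and -31.1 points), but the cytosine outside the most different CpG of the Etv4 window differed by -9.05 points.

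At day 0 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7 promoters, all lower in Braf, on 6 regions, and 34 windows, 25 higher and 9 lower. More windows and promoters were called by limma on both scales, and no promoter by edgeR with unconverted reads subtracted. The counts are given in the section on processing. The adjusted p was 0.0109 at Kdm5b, 0.00304 at Tomm5, 0.00734 at Gpi1 and 0.00734 at Prdx2 by the quasi-likelihood test, and 4e-05 at the Cep250 window. The promoter calls depend on which clone is left out: edgeR called 0 without Braf clone 1, without Braf clone 2 or without Braf clone 3 (47, 37 and 37 at an unadjusted p under 0.05), 2 without wild-type clone 2, 14 without wild-type clone 1 and 9 without wild-type clone 3. The lowest adjusted p by the quasi-likelihood test among Kdm5b, Prdx2, Rnaseh2a, Tomm5 and Gpi1 was 0.317 without Braf clone 1, 0.708 without Braf clone 2 and 0.275 without Braf clone 3, and without wild-type clone 2 it was 0.102 at Prdx2 and Rnaseh2a and 0.105 at Gpi1. Where these calls were lost, the differences stayed at -20.7 to -21.7 points for Kdm5b, -21.0 to -23.6 for Prdx2, -17.1 to -17.7 for Tomm5 and -17.0 to -17.5 for Gpi1, and without wild-type clone 1 or 3 every named promoter kept its call. Windows numbered 7 without Braf clone 1, 16 without Braf clone 2, 6 without Braf clone 3, 2 without wild-type clone 1, 1 without wild-type clone 2 and 29 without wild-type clone 3. Only the Cep250 window kept its call in all of these, and it rests on 1 CpG: its most different cytosine was 92.6 points higher in Braf and the 1 outside that CpG differed by -0.742 points. Each other named window lost its call in at least 5 of the 6, at differences that stayed at 49.9 to 56.4 points for the higher ones and -45.6 to -29.9 for the lower ones. Braf, Cdkn2a, Cdkn2b and Igfbp7 differed by -0.872 to -0.12 points.

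At day 21 most of the same genes were called, and the DNA repair gene Mgmt and the ribosome assembly gene Rrp12 as well. Mgmt was higher in Braf (91.9% ± 5.23 against 63.4% ± 8.26, at chromosome 7, 137127693 to 137129193), and it belongs to the lists of methylator phenotype markers and of tumour suppressors. It had already been at 88.9% against 66% at day 0. The annotation gives no strand, so this region may not hold the start of Mgmt. Rrp12 was lower in Braf (33.9% ± 4.18 against 78% ± 9.62; already 30.4% against 69.5% at day 0), as were Prdx2 and Rnaseh2a (-19.3 points), Kdm5b (-18.3 points) and Gpi1 (-18.2 points). Among the windows higher in Braf that near Cep250 was again the furthest apart (91.1% against 24.7%), though the cytosine outside its most different CpG differed by -0.0496 points, followed by windows near Gm52512 (51.9 points) and Ust, a gene of dermatan sulfate synthesis (48.6 points). Of the 33 higher windows, 24 fell under 10 points without their most different cytosine, and of the 32 lower ones 5. On the lower side were a window near Rrp12 (-67.3 points; at 15.9% against 78.6% at day 0) and the 2 Meis1 windows (-54.4 and -46.8 points), which were not called at day 0. The Rrp12 window had 0.226 times as many reads in Braf as in wild type, where the 5th percentile over all windows was 0.722. Windows in Bicc1 (-35.1 points), Dusp5 (-33 points), Slc25a48 (-27.1 points) and Tgif2 (-14.5 points) were lower and one in Zfp566 higher (28.5 points), all 5 named after their values were seen.

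At day 21 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9 promoters (1 higher, 8 lower, on 8 regions) and 65 windows (33 higher, 32 lower), 30 of these windows at both days. As at day 0, limma called more of both on both scales, and edgeR with unconverted reads subtracted called no promoter. The adjusted p by the quasi-likelihood test was 0.0435 at Mgmt, 0.0111 at Rrp12, 0.0111 at Kdm5b and 0.0055 at Gpi1. Of the 32 lower windows, 17 had differed by under 10 points at day 0, and 16 of these had gained at least 10 points in wild type. The promoter calls depend on which clone is left out: edgeR called 0 promoters without Braf clone 1, without Braf clone 2 or without Braf clone 3 (97, 84 and 59 at an unadjusted p under 0.05), 3 without wild-type clone 2, 16 without wild-type clone 1 and 49 without wild-type clone 3. At Mgmt the difference was -0.683 points with at least 30 reads per cytosine (adjusted p = 0.9998 by the quasi-likelihood test). The gene end was chosen anew at that minimum, so this value may come from the other end of Mgmt. The adjusted p of the quasi-likelihood test at Mgmt was 1 without Braf clone 1, 0.9999 without Braf clone 2, 0.273 without Braf clone 3 and 0.138 without wild-type clone 2. At Rrp12 the quasi-likelihood test gave an adjusted p of 0.287 without Braf clone 1, 0.718 without Braf clone 2, 0.369 without Braf clone 3 and 0.111 without wild-type clone 2. For Prdx2, Rnaseh2a, Kdm5b and Gpi1 the lowest adjusted p by the quasi-likelihood test was 0.287 without Braf clone 1, 0.654 without Braf clone 2 and 0.285 without Braf clone 3, and without wild-type clone 2 it was 0.138 at Prdx2 and Rnaseh2a and 0.0777 at Gpi1. Where these calls were lost, the differences stayed at -18.0 to -18.3 points for Gpi1, -19.0 to -19.5 for Prdx2, -18.0 to -18.9 for Kdm5b, -42.3 to -46.4 for Rrp12 and 26.8 to 31.5 for Mgmt, and without wild-type clone 1 or 3 every named promoter kept its call. Windows numbered 7 without Braf clone 1, 10 without Braf clone 2, 4 without Braf clone 3, 3 without wild-type clone 1, 2 without wild-type clone 2 and 44 without wild-type clone 3. Among the named windows only that near Cep250 kept its call throughout, and the smallest difference where a call was lost was -12.7 points, at Tgif2.

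Mean CpG methylation was close in the 4 groups: 44.7% ± 1.72 and 45.3% ± 2.48 in wild type at day 0 and day 21, and 44.1% ± 0.657 and 43.8% ± 1.00 in Braf (SD, n = 3). The change was -0.360 points in Braf (exact permutation p = 0.25, two-sided, the smallest possible with 3 pairs) and 0.647 in wild type (exact permutation p = 0.5). Their difference was -1.01 points (exact permutation p = 0.3, two-sided), and the genotypes differed by -0.545 points at day 0 (exact permutation p = 0.9) and -1.55 at day 21 (exact permutation p = 0.6). Without wild-type clone 3 the change in wild type was 0.175 points, the difference of changes -0.534, and the genotypes differed by 0.415 points at day 0 and -0.119 at day 21. Cytosines from 20% to 80% had a change of -1.24 points in Braf and 1.52 in wild type (difference -2.75, exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). Cytosines under 20% were higher at day 21 in all 6 clones (0.971 points in Braf, 1.36 in wild type), and those at 80% or more were lower in all 6 (-1.59 and -0.724 points). Under 20%, the larger wild-type mean rests on clone 3 (2.40 points), whose non-CpG share also rose by 1.83 points. Wild-type clones 1 and 2 changed by 0.977 and 0.712 points there, and the Braf clones by 0.691 to 1.18.

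The X chromosome, of which 1 copy is silent and methylated at its CpG islands in female cells, was also taken alone. Cytosines of X had changes of -3.32 points in Braf and -2.11 in wild type, lower at day 21 in all 6 clones, while its 319 promoters were higher in all 6 (1.25 and 1.59 points), against means of 0.935 and 1.31 points over all promoters. For the X promoters the exact permutation p was 0.25 in each genotype, the smallest possible with 3 pairs, and the difference of -0.340 points had an exact permutation p of 1, two-sided. Wild-type clone 3 had a change of 3.68 points; without it the wild-type change was 0.547 points and that difference 0.706 (exact permutation p = 0.1).

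Cytosines outside CpG read as methylated made up 0.140% to 6.77% of non-CpG reads in a library. Wild-type clone 3 had the most, 4.94% at day 0 (95% confidence interval 4.94% to 4.95%) and 6.77% at day 21 (6.77% to 6.77%; both intervals count every read as independent and cover counting error alone), and mitochondrial DNA, which carries little methylation, gave similar shares. The change was 0.161 points in Braf (exact permutation p = 0.5, two-sided) and 0.585 in wild type (exact permutation p = 0.75), with a difference of -0.423 (exact permutation p = 0.9), and the genotypes differed by -0.875 at day 0 and -1.30 at day 21 (exact permutation p = 1 for each). The wild-type change was 1.83 points in clone 3 against 0.00458 and -0.0767 in the others, and without clone 3 the difference of changes was 0.198 (exact permutation p = 0.3). Braf clone 3 is laid out unlike the others: opposite-strand reads cover 59.8% and 59.9% of its CpG cytosines, against 24.3% to 27.7% in the other libraries.

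**Figure D3:**
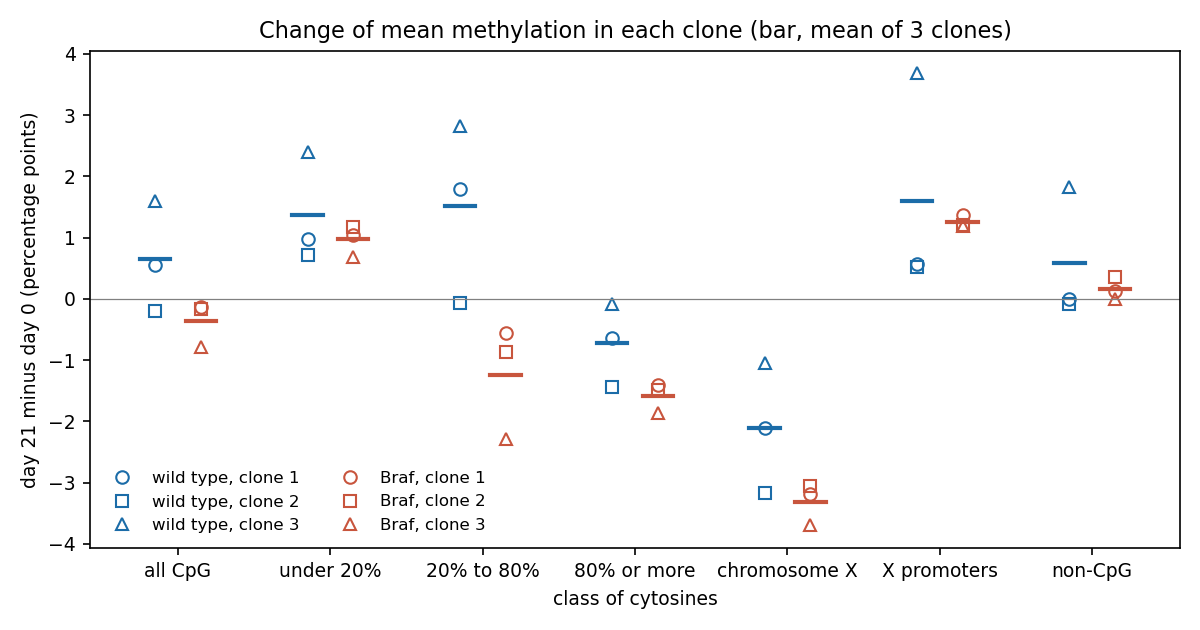
Change in mean methylation from day 0 to day 21 by class of CpG cytosines, 1 point per clone.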

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

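The tests on the clones of the other genotype, with unconverted reads subtracted, on single cytosines and on read ratios were chosen only after the results they bear on had been seen; thinned reads, clones left out, other splits and the exact permutation test were planned, and were set against these explanations afterwards.

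Windows near or in 6 genes stood out because all 3 clones of a genotype moved one way between day 0 and day 21 and all 3 of the other the opposite way. All but that near Zfp954 had been picked for a low p-value for this same difference, with clone changes that did not overlap. That choice favours such a pattern, and how many of all windows show it was not counted. The Braf change minus the wild-type change was -27.8 points in Hbegf, an EGF receptor ligand gene (chromosome 18, 36514201 to 36514400), -13.5 in Irf2bpl (chromosome 12, 86881801), 22.1 near Ptpru (chromosome 4, 131696201), 30.2 in Rbm47 (chromosome 5, 66075001), 16.2 near Fshr (chromosome 17, 89311201) and -7.03 near Zfp954 (chromosome 7, 7077201). None of them passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for the difference of changes: the adjusted p was 0.197 for the first 5 and 0.72 near Zfp954. Non-CpG cytosines, which no comparison of regions uses, were read as methylated in 4.94% (day 0) and 6.77% (day 21) of reads of wild-type clone 3, more than 2 times the highest share in any other clone.

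Windows such as those at Cdkn2a and Dlx1 gained methylation by day 21 in both genotypes. Incomplete bisulfite conversion at day 21 is argued against as the whole cause, because the 2 clones whose non-CpG share did not rise still had a lowest median change of 9.501 points at the windows that gained in the other genotype. With unconverted reads subtracted edgeR called 1598 gains in Braf and 2902 in wild type, against 4335 and 6173. It called 0 promoters in each (1280 and 1188 at an unadjusted p under 0.05), where limma on percentages called 168 and 217. The estimated dispersion of promoters rose from 0.00988 to 0.489, and whether this ended the calls was not tested. The change at the Dlx1 promoter in Braf was 31.2 points before and 31.4 after. Unequal depth is argued against as well, since 4310 windows gained in Braf after all libraries were thinned to the same reads, against 4335 before. What else stays open is biological and was not tested: 4-OHT, Cre activity, 21 days of culture and selection of cells came together in every clone, with no library of untreated cells at day 21.

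Calls in wild type were mostly gains (78.5%), while those in Braf were divided (54.5% gains), and its largest losses, near Tafa5 and Cdh9, lay far from genes. Incomplete conversion in wild-type clone 3 is argued against, since without it 77.88% of wild-type calls were still gains. The unusual read layout of Braf clone 3 is argued against as the whole cause, since without it gains made up 62.11% of Braf calls. Chance differences between 6 clones stay open: over cytosines from 20% to 80% the difference between the clone changes had an exact permutation p of 0.1, the smallest that 3 against 3 can give. An effect of the activated Braf allele, which the design would allow, stays open too. It cannot be told apart here from such chance or from other differences between the clones of the genotypes.

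Before 4-OHT, 25 windows, led by that near Cep250, were higher in Braf and 9, such as that near Ctnnbl1, were lower. A sequence variant at 1 CpG is a possible source for 15 of the 25 higher ones. In these a single cytosine was 80 points or more higher in Braf, against 0 of 4335 gains and 0 of 3619 losses in Braf over time. The rest still differed by 14.2 points at chromosome 4, 132452001, and by 16.3 and 18.6 points at chromosome 11, 76463601 and 89114601. A variant at 1 CpG does not account for the windows near Zfp954 and Gm52512, where the other cytosines differed by 52.7 and 52.2 points. These windows share a CpG spacing of 4, 8 and 10 bp and may be copies of 1 sequence. This could not be checked without a genome sequence. Leaving out 906 cytosines with over 10% A on the opposite strand is not among the alternatives listed below as moving the day 0 count. That filter needs 10 opposite-strand reads, which 15.5% to 54.9% of cytosines had in a library. For 7 of the lower ones a variant is argued against, since only 2 of 9, that near Etv4 among them, fell under 10 points without the cytosine that differed most, and extra methylated copies of the sequence in wild type stay open (1 of 9 had an unusually low read ratio). The 17 windows lower in Braf only at day 21, which include those in Meis1, were chosen for differing by under 10 points at day 0, so a variant, which would show at both days, was not tested on them. The strain is given as mixed, so different parents of the embryos remain an untested explanation. Some of the day 0 windows lie close together on chromosome 2, at 155988201, 156096201, 156136001 and 156505801 (higher in Braf) and 157696601 (lower). The Tgif2 window (156842401) and the Nnat promoter (157559078), named above for the difference of changes, lie in the same stretch. Whether different parents played a part at either was not tested.

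The 6 libraries of each comparison of 2 groups, and the 6 clones for the difference of changes, can be split into groups of 3 in 10 ways, too few for a share under 0.05. For day 21 against day 0 in Braf, 1 of 10 splits, the real one, called 7954 windows (highest other 0), 199 promoters (highest other 0) and 9 gene lists (highest other 5, and 1 among the 4 splits that also part all 3 pairs). In wild type 1 of 10 splits, again the real one, called 7867 windows (highest other 0), 271 promoters (highest other 0) and 10 gene lists (highest other 6, and 5 among the 4 that part all pairs). For the difference of changes the real split called 0 windows (highest other 0), 0 promoters (highest other 2) and 0 gene lists (highest other 2). All 10 of 10 splits reach a count of 0 whatever the data, so these counts decide nothing. At day 0, 1 of 10 splits called 34 windows (highest other 0) and 7 promoters (highest other 0), and at day 21, 1 of 10 called 65 windows (highest other 0) and 9 promoters (highest other 0). For the difference of changes the real split had 8205 windows at an unadjusted p under 0.05 by edgeR, the most of the 10. The other splits had 4072 to 6090. For promoters the real split had 380 and the others 267 to 909. In the real split limma called 0 windows and 0 promoters.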

How the results depend on the processing

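Every alternative that subtracts unconverted reads, joins no block with limma, leaves out clones 3, tests both gene ends, enters each region once or leaves a clone out of the non-CpG values was chosen after seeing the data. The others were planned, and the cause of a change was not tested unless the alternative itself shows it (fewer samples, another size of difference). Counts within 1.5 times the value reported are left out here: 66 of 103 alternatives for windows, 77 of 108 for promoters and 20 of 27 for gene lists; 46 of 49 for global methylation, 20 of 21 for X promoters and 5 of 6 for non-CpG values kept direction and side of the threshold. A difference of 20 points left 1502 windows in Braf, 1999 in wild type, and 31, 55, 4 and 3 promoters in Braf, in wild type, at day 0 and at day 21, while no minimum gave 18510 and 18218 windows and 1719 and 1797 promoters. Without the block edgeR called 2673 and 2896 windows, 0 promoters in Braf (347 at an unadjusted p under 0.05) and 13 in wild type, and 3 gene lists for the difference of changes. Without the block limma on percentages called 4656 and 4652 windows. With unconverted reads subtracted edgeR called 3096 and 3553 windows and 0 promoters in Braf, in wild type, at day 0 and at day 21 (1280, 1188, 292 and 366 at an unadjusted p under 0.05), and limma on percentages then called 112 windows at day 0 and 550 windows and 17 promoters at day 21. limma on log ratios called 222 windows and 26 promoters at day 0 and 444 and 37 at day 21; on percentages 186 and 28, and 417 and 82. Windows of 1000 bp gave 3 for the difference of changes, 59 at day 0 and 198 at day 21, and thinned reads 1 and 17 for the first 2. Numbers paired across genotypes gave 16 windows and 20 promoters at day 0 and 24 and 36 at day 21. Without clones 3, 1 window was called at each day. With an estimated correlation 0 gene lists passed camera in Braf and 0 in wild type (1 and 2 at an unadjusted p under 0.05). Reversed values were global methylation in Braf at 30 reads (0.271 points) and at day 0 with pooled reads (0.764). The promoters of Ptpn3 in wild type at 5 reads (0.592) and of Mgmt at day 21 at 30 reads (-0.683) reversed as well. At these minimums the gene end was chosen anew, so either promoter value may come from the other end. Without wild-type clone 3 the day 0 difference of global methylation (0.415), the difference of X promoters (0.706) and that of non-CpG values (0.198) reversed. Leaving out 1 clone gave 4964 to 8167 windows in Braf, 5768 to 7836 in wild type, 0 to 0 for the difference of changes, 1 to 29 at day 0 and 2 to 44 at day 21; 156 to 205, 229 to 268, 0 to 2, 0 to 14 and 0 to 49 promoters; and 4 to 9, 9 to 10 and 0 to 2 gene lists. Global methylation then ran from -0.472 to -0.146 points in Braf, 0.175 to 1.07 in wild type, -1.43 to -0.534 for the difference, -1.23 to 0.415 at day 0 and -2.29 to -0.119 at day 21; X promoters from 1.19 to 1.28, 0.547 to 2.13 and -0.875 to 0.706; the non-CpG difference from -0.754 to 0.198. Of the named promoters 2023 values kept direction and side, 380 lost the call, 3 gained it and 2 reversed, and of the named windows 754, 137, 1 and 0. Depth limits mainly which cytosines enter: 1248937 at 5 reads, 657358 at 30.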

Other observations

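All the tests in this part were chosen only after the results they bear on had been seen.

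Hbegf, a ligand gene, and Dusp5, a phosphatase gene of the MAPK list, had windows with low p-values for the difference between the genotypes' changes. This raised the hypothesis that genes of the MAPK pathway differ more often than others. Hbegf itself is on the list of inflammatory and secretory genes and not on the MAPK list. The windows in or near genes already singled out for this difference were left out of both tests here. Of the remaining 244 windows in or near genes of the MAPK list 9.836% had p under 0.05 for that difference, against a median of 7.527% over 10000 random gene lists (permutation p = 0.2246, two-sided), so the data do not decide.

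Meis1, Meis2 and Tgif2 raised the hypothesis that windows of developmental transcription factors differ more often in change. Of the remaining 1244 windows of that list 10.93% had p under 0.05, against a median of 8.023% over random lists (permutation p = 0.0048, two-sided; adjusted p = 0.0304 over 19 lists). Hox genes (21.17%, permutation p = 0.0002, adjusted 0.0019) and cell cycle inhibitors and senescence genes (17.43%, permutation p = 0.0002, adjusted 0.0019) passed as well. On promoters none of these 3 lists passed for the same difference: camera's adjusted p was 0.720, 0.234 and 0.600, and that of fry 0.872 for each. The random lists were matched on the number of windows and not on methylation level, and neighbouring genes such as the Hox clusters share windows, so these p-values are likely too small (0.0048 for the developmental factors included).

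Promoters on X gained while its other cytosines lost methylation, which loss or gain of an X chromosome in culture could bring about. Of the 6 clones, the ratio of the X share of reads at day 21 to that at day 0 that lay farthest from 1 was 1.046, in wild-type clone 1, which argues against a lost or gained copy in most cells.

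Windows around Meis1 numbered 23, of which 8 were called in Braf and 4 in wild type, all as gains; around Cdkn2a there were 14, of which 6 and 7 were called. Of the 25 windows higher in Braf at day 0, 4 share the same CpG spacing of 4, 8 and 10 bp. They are those near Zfp954, Gm52512 and Ust and that at chromosome 4, 101870601. They may be copies of 1 sequence and not separate differences, which was not tested.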
